A study of Homo sapiens with 12 samples.

How the data were processed

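Gene expression was measured by RNA sequencing of total RNA from 12 libraries of A549/DDP cells, 3 in each of 4 groups: shNC DMSO, shNC GNA, shNRF2 DMSO and shNRF2 GNA. Single-cell RNA sequencing named in the series description was not analysed here. The authors deposited a table of raw counts and a table of FPKM values, each with 61510 genes and the same 12 libraries. Per the labels, the processing used the GRCh38 build and DESeq2, whose role and version are not stated. The aligner, the counting tool and the annotation release are not given in the sources used here. The deposited FPKM values were counts divided by the column total and by a fixed length per gene, within a relative tolerance of 0.001 for 100% of 12982 genes checked. They therefore hold no information beyond the deposited counts and were used only as an alternative unit.

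All columns were mapped to a group by their titles. Library totals ran from 12848607 to 17192671 counts, and 23496 of the 61510 genes had no count in any library. Genes were filtered with filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 15653 genes holding 99.8% of the counts. Counts were scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with 1 coefficient per group and 8 residual degrees of freedom. The 5 comparisons were GNA against DMSO in each line, shNRF2 against shNC in each treatment, and the difference of the GNA response between the lines. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The SE of a log2 fold change was its size divided by the square root of the F statistic, and 95% intervals used 8 degrees of freedom. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1. Levels are CPM on TMM-scaled totals.

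The comparisons, tests, 24 gene lists and naming rule were fixed before the data were examined. The rule named 12 fixed genes, the 6 largest rises and falls in each comparison, and up to 3 called genes each way per described list. Those 6 were taken from called genes with an approved symbol, at least 5 CPM in the higher group and, except for the difference of responses, no overlap between the libraries compared. The report names a part of the genes under this rule. Which part was chosen after their values were seen, and genes whose level in single libraries drove the change were left out. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation. Camera compares a list with the other genes. The lists were also tested with fry, which tests a list against no change, a different question. The lists overlap in a few genes, such as HMOX1, SLC7A11, FTL and FTH1, which are in both the NRF2 target and the iron lists. Near-identical copies (HSPA1A and HSPA1B, the AKR1C and metallothionein genes, FTH1 and FTL, ribosomal protein genes) can exchange reads. Positions are from GENCODE 29 on GRCh38.

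The test was checked on simulated data with the real spread: for GNA in shNC it recovered 58.0% of 1.5-fold and 76.5% of 2-fold changes, and for the difference of responses 37.2% and 62.5%. In those simulations 10.7% and 9.52% of the calls were false, above the nominal 5%. For GNA in shNC the simulation changed 100 tested genes by 1.5-fold and 98 by 2-fold and gave 149 calls, against 4810 in the data. For the difference of responses it changed 94 and 96 and gave 105 calls, against 1068 in the data. The call threshold depends on how many genes change, so these percentages need not hold for the data. The alternatives tried were DESeq2 size factors, upper-quartile factors and library totals in edgeR, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), replicate number as a block, only the groups compared, and leaving out each library in turn. Library totals were added after the data were seen. Library shNC DMSO 1 stood apart from the 2 others of its group, with a chi-square per degree of freedom of 8.02 and 6.30 against 3.73 between those 2; in the other groups the values ran from 2.28 to 5.30. Replicate numbers did not pair the libraries: of 18 pairs with the same number in different groups 3 had a residual correlation over 0.1, and 5 of 12 libraries correlated best with a library of their own number.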

Results

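RNA sequencing was done on A549/DDP cells, a cisplatin-resistant derivative of the human lung adenocarcinoma line A549, grown in medium with 1 µg/ml cisplatin. One line carried a control short hairpin RNA (shNC) and the other a hairpin directed at NRF2 (shNRF2), the transcription factor encoded by NFE2L2 that turns on antioxidant and detoxification genes. Both lines were given DMSO or 4 µM gambogenic acid (GNA), a caged xanthone from gamboge resin, at 70% confluence and were collected after 24 h. There were 3 libraries in each of 4 groups, 12 in all. The series title asks about NRF2, the heat shock factor HSF1 and heme oxygenase 1 (HO-1, encoded by HMOX1) in the action of GNA. Library totals were 15118635 to 17192671 counts in shNC DMSO, 13599974 to 15896846 in shNC GNA, 13158101 to 15776177 in shNRF2 DMSO and 12848607 to 15637944 in shNRF2 GNA. Between 23429 and 25086 genes had at least 1 count. The first principal component took 45.7% of the variance and separated GNA from DMSO within each line, and the second, with 35.3%, separated the lines within each treatment. Levels below are CPM (counts scaled to the TMM-adjusted library total), mean ± SD of 3 libraries. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test, called at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

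NFE2L2, on chromosome 2 at 177227595 to 177392697 (GRCh38, minus strand), was lower in the shNRF2 line in every library. It stood at 77.9 ± 3.60 CPM in shNC DMSO, 87.4 ± 3.85 in shNC GNA, 50.2 ± 2.80 in shNRF2 DMSO and 45.8 ± 2.00 in shNRF2 GNA. The deposited FPKM values were 4.96 ± 0.260, 5.97 ± 0.275, 3.31 ± 0.181 and 3.16 ± 0.121 in the same order. The hairpin line kept 64.3% of the control level in DMSO (log2 fold change -0.64 ± 0.064, edgeR adjusted p = 1.2e-08) and 52.4% in GNA (-0.93 ± 0.064, edgeR adjusted p = 9.0e-12). With GNA, NFE2L2 changed by 0.17 ± 0.061 in shNC (edgeR adjusted p = 0.041) and by -0.13 ± 0.066 in shNRF2 (adjusted p = 0.13). The difference of those responses was -0.30 ± 0.090 (edgeR adjusted p = 0.045). The calls in shNC and for the difference are marginal: both were lost without the low-count filter (adjusted p = 0.073 and 0.068), with replicate number as a block (adjusted p = 0.057 and 0.066) and when single libraries were left out. The first was lost without shNC DMSO replicate 2 (adjusted p = 0.090) or 3 (0.17) and without shNC GNA replicate 1 (0.10) or 3 (0.15), and with DESeq2 (adjusted p = 0.065). Among the fits without 1 library, the second was kept without shNC DMSO replicate 1, shNC GNA replicate 2 or shNRF2 DMSO replicate 1 (adjusted p = 0.023, 0.049 and 0.046) and lost without each of the 9 others (0.055 to 0.14). It was also lost with limma on FPKM (0.082 and 0.086). KEAP1, whose product sends NRF2 to degradation, was also lower in shNRF2, at -0.61 ± 0.089 in DMSO and -0.35 ± 0.088 in GNA.

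**Figure D1:**
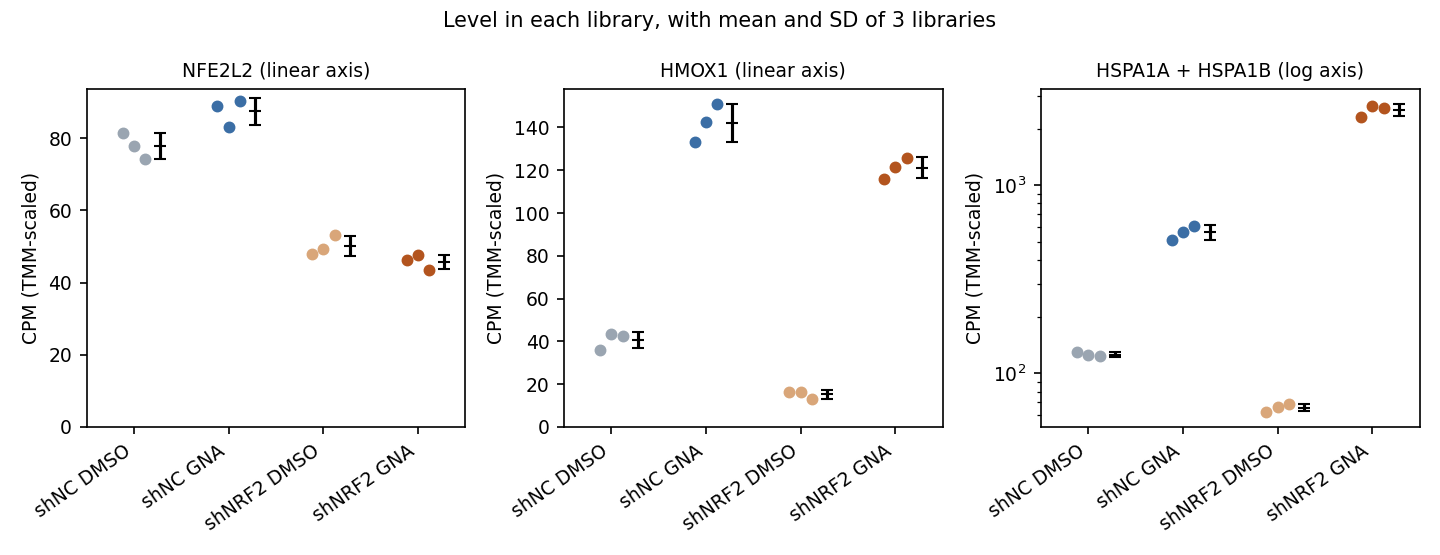
CPM of NFE2L2, HMOX1 and the sum of HSPA1A and HSPA1B in each of the 12 libraries, by group; points are libraries, and the bar with whiskers is the mean ± SD of 3. The first and second panels have linear axes from 0 and the third a log axis. HMOX1 lies at 15.1 CPM in shNRF2 DMSO and 121 CPM in shNRF2 GNA, and the HSPA1A and HSPA1B sum at 65.7 and 2507 CPM.

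In shNC cells, GNA raised integrated stress response genes, HMOX1 and part of the heat shock genes and lowered genes of DNA replication and mitosis. HSPA6, a strictly inducible HSP70 gene, went from 0.175 ± 0.105 to 64.0 ± 3.19 CPM; no fold is given against so few counts. BEX2 rose from 5.61 ± 0.976 to 66.9 ± 3.04 CPM (3.57 ± 0.11) and the small heat shock protein gene CRYAB from 1.42 ± 0.214 to 11.3 ± 1.42 (2.99 ± 0.20). NIBAN1 rose from 41.5 ± 3.58 to 233 ± 8.19 CPM (2.49 ± 0.061, edgeR adjusted p = 4.5e-21). HMOX1, the heme-degrading enzyme HO-1 on chromosome 22 at 35380361 to 35394214, rose from 40.6 ± 3.86 to 142 ± 8.87 CPM (1.81 ± 0.073, edgeR adjusted p = 3.0e-16). Among the steepest falls were FAM111B (-1.64 ± 0.085), the mitotic kinesin KIF20A (-1.36 ± 0.089), MYH15 (-1.35 ± 0.084), ERCC6L (-1.34 ± 0.15) and ZBED2 (-1.30 ± 0.062).

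All 24 measured genes of the integrated stress response, the program driven by ATF4, rose in shNC (median 1.20, camera adjusted p = 3.6e-84). NUPR1 rose by 2.23 ± 0.070, PCK2 by 2.10 ± 0.098 and DDIT3, which encodes CHOP, by 2.05 ± 0.085. ATF3 rose by 0.99 ± 0.058 and CHAC1 went from 0.460 ± 0.314 to 4.16 ± 0.468 CPM, too few counts for a fold. All 26 genes of DNA replication and S phase fell (median -0.84, camera adjusted p = 5.0e-38), FEN1 by 1.09 and CCNE2 by 1.20 on the log2 scale. All 23 measured genes of mitosis and G2/M fell too (median -0.96, camera adjusted p = 5.4e-58), among them PLK1 (-1.21 ± 0.079) and CDC20 (-1.24 ± 0.15). The heat shock list was divided: 13 of 27 genes rose (14 adjusted over the list alone) and 8 fell (median 0.20, camera adjusted p = 7.3e-14). Its risers included HSPA1A (2.17 ± 0.063) and the HSP40 gene DNAJB1 (0.67 ± 0.055), and its fallers the chaperone genes HSPA4 (-0.33 ± 0.043), AHSA1 (-0.26 ± 0.050) and CACYBP (-0.25 ± 0.053). HSF1 itself changed by 0.27 ± 0.10 (edgeR adjusted p = 0.046), a call lost with DESeq2 (adjusted p = 0.093) and without shNC DMSO replicate 1 or 2 (adjusted p = 0.070 and 0.20) or shNC GNA replicate 2 or 3 (0.097 and 0.20).

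NRF2 target genes did not move together with GNA in shNC: 15 of 34 rose and 14 fell (16 adjusted over the list alone; median 0.069, camera adjusted p = 0.87). Beside HMOX1, OSGIN1 (0.86 ± 0.093) and the cystine transporter gene SLC7A11 (0.52 ± 0.048) rose, and TKT (-0.62 ± 0.043), GPX2 (-0.58 ± 0.057), AKR1C1 (-0.56 ± 0.049) and NQO1 (-0.24 ± 0.047) fell. In the NF-kB and inflammatory list 9 of 20 genes fell and 0 rose (1 adjusted over the list alone; camera adjusted p = 1.7e-05), with CCL2 at -1.20 ± 0.081, CXCL5 at -0.85 ± 0.041 and ICAM1 at -0.74 ± 0.096. Of 24 p53 target genes 10 rose (11 adjusted over the list alone) and 1 fell (camera adjusted p = 0.0065), led by GADD45A (0.70 ± 0.056) and PHLDA3 (0.61 ± 0.073). 4 of 20 hypoxia and glycolysis genes rose and 11 fell (camera adjusted p = 0.023, adjusted p = 0.091 with an estimated correlation). NDRG1 (0.83 ± 0.077) and VEGFA (0.73 ± 0.053) were up there and the glycolytic LDHA (-0.81 ± 0.046), TPI1 (-0.55 ± 0.055) and PKM (-0.51 ± 0.045) down. 8 of 25 cholesterol synthesis genes fell and 0 rose, among them HMGCS1 (-0.65 ± 0.059) and EBP (-0.94 ± 0.097), with a camera adjusted p = 0.012 and an adjusted p = 0.13 with an estimated correlation.

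The keratin genes KRT8 (-0.71 ± 0.040) and KRT18 (-0.65 ± 0.044) fell, while CDH1 (0.46 ± 0.080) and OCLN (0.52 ± 0.074) rose. As a list, epithelial genes had a median of 0.19 and a test in the other direction (camera adjusted p = 0.85). 8 of 20 mesenchymal and matrix genes rose (9 adjusted over the list alone) and 2 fell, with LOXL2 at 0.54 ± 0.079 (camera adjusted p = 0.0065, adjusted p = 0.30 with an estimated correlation). Of the iron and ferroptosis genes 7 of 20 rose and 5 fell (camera adjusted p = 0.030, adjusted p = 0.091 with an estimated correlation). That call was lost without the low-count filter (adjusted p = 0.14), with limma on FPKM (0.15 and 0.16) and without shNC GNA replicate 1 (0.059). The ER chaperone list also holds other unfolded protein response genes, such as HERPUD1 and SYVN1. Its genes fell in 9 (10 adjusted over the list alone) and rose in 6 of 20 cases (camera adjusted p = 0.029, adjusted p = 0.35 with an estimated correlation), with MANF at -0.80 ± 0.054 and CALR at -0.58 ± 0.045. The ER chaperone call was also lost with limma on FPKM (adjusted p = 0.14 for both), with only the 2 groups compared (0.060) and without shNC DMSO replicate 1 (0.079) or shNC GNA replicate 1 (0.059). 10 of 13 mitochondrially encoded messenger RNAs fell, MT-ND3 by 0.59 (camera adjusted p = 1.5e-05, adjusted p = 0.35 with an estimated correlation). Together they took 5.21 ± 0.678% of counts in shNC DMSO and 4.67 ± 0.194% in shNC GNA. Much of that fall lies in shNC DMSO replicate 1, at 5.98%, while replicates 2 and 3 (4.71 and 4.95%) overlap the 3 GNA libraries (4.46 to 4.83%). Without it the list median went from -0.34 to -0.24 and the list was still called (adjusted p = 7.4e-04). 15 of 30 ribosomal protein genes were lower (17 adjusted over the list alone; camera adjusted p = 4.9e-04, adjusted p = 0.58 with an estimated correlation).

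Camera with the preset correlation made no call on the edgeR fit in shNC for proteasome subunits (5 higher and 6 lower of 31), autophagy and lysosome genes (8 and 5 of 24, 9 and 6 adjusted over the list alone), the BCL2 family (2 and 4 of 14), interferon-stimulated genes (3 and 7 of 23, 4 higher adjusted over the list alone) or immediate early genes (8 and 4 of 20). The same held for cisplatin transport and repair genes (8 and 5 of 24), the metallothionein list (2 and 0 of 4), alveolar type 2 genes (1 and 1 of 4) and the fibroblast, endothelial and leukocyte markers (0 and 1 of 4). Measured members of the metallothionein list were MT1X, MT2A, MTF1 and SLC30A1, of which MTF1 and SLC30A1 are not metallothionein genes. The autophagy list was close (camera adjusted p = 0.055) and passed with DESeq2 (adjusted p = 0.0024), library totals (0.013), upper-quartile factors (0.035), only the 2 groups compared (0.047) and without shNC DMSO replicate 2 (0.049) or 3 (0.032). Over the alternatives of this test its adjusted p ran from 0.0024 with DESeq2 to 0.22 with an estimated correlation. Interferon-stimulated genes passed with DESeq2 (adjusted p = 0.017). Where this text gives no count adjusted over the list alone, it equals the count over all genes. The test pointed down although the median was above 0 for the BCL2 family (0.017), interferon-stimulated (0.0062) and alveolar type 2 genes (0.13), and for proteasome subunits the median was -0.024 and the mean 0.019. Over all 15653 genes tested, 2284 were higher and 2526 lower with GNA in shNC, of which 343 and 120 changed at least 2-fold. Scaling by library totals, which moved the median of all genes by 0.10, gave 3543 higher and 1542 lower, and the ER chaperone and hypoxia list calls ended (adjusted p = 0.18 and 0.068). The share of genes whose 3 GNA and 3 DMSO libraries did not overlap was 40.7%, where chance gives 10%.

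In shNRF2 cells, GNA raised nearly the whole heat shock list. HSPA6 went from 0.0684 ± 0.0646 to 224 ± 5.20 CPM. HSPA1A and HSPA1B, near-identical HSP70 genes on chromosome 6 at 31815464 to 31817946 and 31827735 to 31830255, rose by 5.28 ± 0.072 and 5.06 ± 0.091. Reads of these genes cannot be fully told apart, so their sum is given too, which went from 65.7 ± 2.90 to 2507 ± 186 CPM. In all 26 of 27 heat shock genes rose and 0 fell (median 0.90, camera adjusted p = 3.4e-122), with DNAJB1 at 2.34 ± 0.056. HMOX1 rose from 15.1 ± 1.90 to 121 ± 4.96 CPM (3.00 ± 0.084, edgeR adjusted p = 2.4e-20). BEX2 (4.37 ± 0.11) and CRYAB, from 0.857 ± 0.147 to 10.9 ± 1.82 CPM (3.65 ± 0.22), were among the other large rises. BEX4 went from 0.345 ± 0.175 to 6.17 ± 0.815 CPM, without a fold for the same reason as HSPA6. PIF1 (-1.74 ± 0.21), TNFSF15 (-1.72 ± 0.14), NCAPG (-1.64 ± 0.11), PBK (-1.63 ± 0.18) and the noncoding RNA LNCAROD (-1.61 ± 0.099) were among the large falls. HSF1 changed by 0.22 ± 0.11 (edgeR adjusted p = 0.13), and passed only with library totals (adjusted p = 0.046) and without shNRF2 DMSO replicate 1 (0.012) or shNRF2 GNA replicate 2 (0.048).

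The integrated stress response and the cell cycle lists moved in shNRF2 as well. 20 of 24 stress response genes rose (21 adjusted over the list alone) and 0 fell (median 1.13, camera adjusted p = 8.9e-39), with DDIT3 at 2.18 ± 0.078, NUPR1 at 1.81 ± 0.064 and TRIB3 at 1.61 ± 0.098. 25 of 26 S phase genes fell (26 adjusted over the list alone), with RRM2 at -1.36 ± 0.074 and MCM10 at -1.33 ± 0.087 (median -1.02, camera adjusted p = 6.6e-39). All 23 mitotic genes fell, with KIF20A at -1.61 ± 0.092 and CENPF at -1.60 ± 0.055 (median -1.36, camera adjusted p = 5.0e-76). In the autophagy and lysosome list 9 of 24 rose and 1 fell (camera adjusted p = 4.9e-06), led by the autophagy receptor gene SQSTM1 (1.51 ± 0.047), MAP1LC3B (1.35 ± 0.085) and GABARAPL1 (1.28 ± 0.074). 22 of 31 proteasome genes rose (23 adjusted over the list alone), with PSMC4 at 0.73 ± 0.055 and PSMD13 at 0.63 ± 0.058 (camera adjusted p = 3.0e-09, adjusted p = 0.19 with an estimated correlation). 12 of 20 NF-kB and inflammatory genes fell and 3 rose (4 adjusted over the list alone; camera adjusted p = 2.7e-05), CCL2 by 1.57. All 13 mitochondrial messenger RNAs fell (median -0.62, camera adjusted p = 4.5e-14, adjusted p = 0.10 with an estimated correlation), from 5.93 ± 0.427% to 4.21 ± 0.0153% of counts.

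NRF2 target genes went both ways with GNA in shNRF2, with 11 of 34 higher and 15 lower (median 0.013, camera adjusted p = 0.87). HMOX1, SQSTM1 and OSGIN1 (1.30 ± 0.12) were the largest rises and TKT (-0.80 ± 0.044) and AKR1C1 (-0.77 ± 0.050) the largest falls, the AKR1C genes being near-identical copies. 7 of 20 iron and ferroptosis genes rose and 3 fell (4 adjusted over the list alone). FTL (0.74 ± 0.058) and FTH1 (0.53 ± 0.069), the ferritin subunits, were among the risers, both with many processed copies in the genome. That list's median was -0.066, its mean 0.21 and its test upward (camera adjusted p = 0.011, adjusted p = 0.047 with an estimated correlation). The call was lost without the low-count filter (adjusted p = 0.15) and with limma on FPKM (0.20 and 0.19). GADD45A (1.02 ± 0.058) and GDF15 (0.69 ± 0.078) led the p53 targets, of which 9 of 24 rose and 2 fell (camera adjusted p = 0.034, adjusted p = 0.079 with an estimated correlation). ABCB1, the drug efflux pump P-glycoprotein, rose from 16.8 ± 1.18 to 53.8 ± 3.54 CPM (1.68 ± 0.099), while FANCD2 (-0.98 ± 0.11) fell. The cisplatin transport and repair list had 6 genes up and 6 down of 24 (camera adjusted p = 0.87). CCN2 (-1.08 ± 0.097) and THBS1 (-0.92 ± 0.079) fell within a mesenchymal list that went 5 up (6 adjusted over the list alone) and 6 down of 20 (camera adjusted p = 0.82). Median, mean and test also differed in sign, without a camera call, for the BCL2 family (median -0.055, mean 0.14, test up), epithelial genes (0.25, 0.20, down) and the cisplatin list (0.022, -0.067, down). In total 2617 genes were higher and 2657 lower with GNA in shNRF2, 457 and 341 of them at least 2-fold. Library totals gave 3356 higher and 2091 lower. The calls for immediate early genes and the metallothionein list (camera adjusted p = 0.049 for both) were lost with an estimated correlation (adjusted p = 0.44 and 0.12) and with DESeq2 size factors in edgeR (adjusted p = 0.051 for both). Both were also lost without shNRF2 DMSO replicate 1 (adjusted p = 0.095 and 0.086) or shNRF2 GNA replicate 2 (0.061 for both), and the first without shNRF2 DMSO replicate 2 (0.0501) or shNRF2 GNA replicate 1 (0.065).

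**Figure D2:**
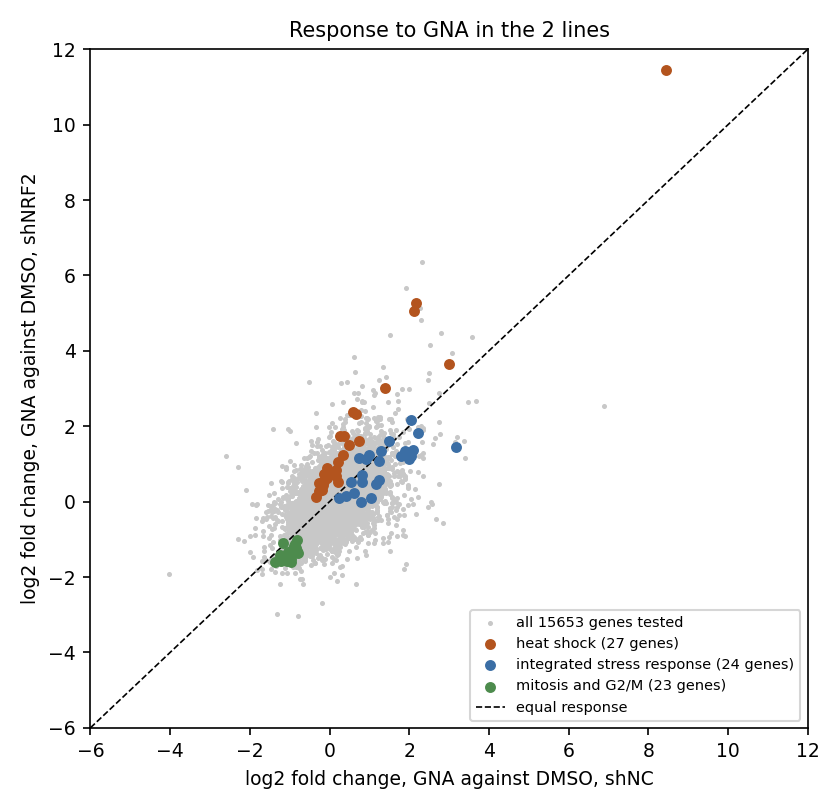
Log2 fold change with GNA in shNC (x axis) against shNRF2 (y axis) for the 15653 genes tested; coloured points are the members of 3 gene lists and the dashed line marks equal responses. All 27 heat shock genes measured lie above the line, and the point at 8.46 and 11.45 is HSPA6, whose DMSO counts are too few for a fold.

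The test of the difference between the lines asked whether the response to GNA depended on the hairpin. Heat shock genes rose more in shNRF2: 25 of 27 had a higher response and 0 a lower one (median difference 0.83, camera adjusted p = 1.5e-164). The difference of log2 changes was 3.11 ± 0.089 for HSPA1A, 2.94 ± 0.13 for HSPA1B and 1.66 ± 0.078 for DNAJB1. The sum of HSPA1A and HSPA1B rose from 125.7 ± 3.25 to 562 ± 48.6 CPM in shNC, a log2 change of 2.16, against 5.25 in shNRF2. HMOX1 differed by 1.19 ± 0.11 (95% interval 0.93 to 1.45, edgeR adjusted p = 5.3e-08), SQSTM1 by 0.94 ± 0.065 and ABCB1 by 1.09 ± 0.14. MYH14, a nonmuscle myosin gene, rose from 21.6 ± 0.414 to 54.5 ± 3.27 CPM in shNC and from 3.40 ± 1.18 to 41.6 ± 3.31 in shNRF2 (2.25 ± 0.17). CCN2 (-1.49 ± 0.14), THBS1 (-1.17 ± 0.11), EGR1 (-1.001 ± 0.10), FOSB (-0.98 ± 0.13) and CCN1 (-0.78 ± 0.11) had lower responses in shNRF2. EGR1 went from 54.0 ± 3.95 to 80.3 ± 5.19 CPM in shNC and from 123 ± 13.0 to 91.3 ± 2.18 in shNRF2. HSF1 (-0.055 ± 0.15, edgeR adjusted p = 0.89) and DDIT3 (0.13 ± 0.12, adjusted p = 0.62) did not pass.

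The stress response list rose less in shNRF2, with 11 of 24 lower (14 adjusted over the list alone) and 1 higher (3 alone; median -0.34, camera adjusted p = 4.4e-08). SLC7A5 (-0.95 ± 0.21, not called with DESeq2) was among the former, and PPP1R15A (0.42 ± 0.063) was the gene that went higher. Mitotic genes fell more in shNRF2 (11 of 23 lower, 19 adjusted over the list alone, median -0.36, camera adjusted p = 5.5e-15), for example CENPF (-0.64 ± 0.076) and TOP2A (-0.57 ± 0.067). S phase genes did so in 5 of 26 cases (9 adjusted over the list alone; camera adjusted p = 9.3e-04). Autophagy genes responded more in 6 of 24 cases (7 adjusted over the list alone; camera adjusted p = 4.1e-06). Proteasome genes did in 20 of 31 (25 adjusted over the list alone), with PSMD11 at 0.59 ± 0.089 and PSMC4 at 0.53 ± 0.077 (camera adjusted p = 2.3e-21, adjusted p = 0.053 with an estimated correlation). The calls for ribosomal protein (median 0.21), mitochondrial (-0.29), mesenchymal (-0.20) and immediate early genes (-0.27) were lost with an estimated correlation (adjusted p = 0.37, 0.22, 0.11 and 0.053). NRF2 target genes showed no shift as a list (5 higher and 5 lower of 34, 8 and 10 adjusted over the list alone, camera adjusted p = 0.62). Signs differed for NRF2 targets (median -0.0032, test up), ER chaperones (median 0.075, mean -0.018, test up) and epithelial genes (median 0.011, test down), none of them called by camera. Over all genes 561 had a higher and 507 a lower response in shNRF2, and library totals gave 414 and 674. Of the 1068 called, 455 changed the same way in both lines and more in shNRF2, 125 the same way and more in shNC, and 488 had fitted changes of opposite sign. With 1 library left out, the count of lower responses ranged from 315 (without shNC GNA replicate 2) to 673 (without shNC DMSO replicate 1). It dropped without most libraries, for example to 330 without shNRF2 DMSO replicate 1, 337 without shNC DMSO replicate 3 and 369 without shNC DMSO replicate 2.

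In DMSO, the shNRF2 line had lower NRF2 target genes, lower heat shock genes and higher ER chaperone and stress response genes than the control line. 28 of 34 NRF2 targets were lower and 2 higher (median -0.85, camera adjusted p = 3.0e-49). The aldo-keto reductase gene AKR1B10 went from 3930.2 ± 123 to 1021 ± 49.2 CPM (-1.94 ± 0.045) and the glutathione peroxidase gene GPX2 from 275 ± 23.9 to 94.4 ± 3.84 (-1.54 ± 0.059). OSGIN1 (-1.61 ± 0.11), HMOX1 (-1.42 ± 0.089), GCLM (-1.16 ± 0.072), TXNRD1 (-0.91 ± 0.043) and NQO1 (-0.61 ± 0.048) were lower, SLC7A11 fell by 0.19 and ABCC3 (0.58 ± 0.059) was higher. Among the largest falls were LINC02582, from 13.4 ± 0.655 to 0.124 ± 0.0923 CPM, the carboxylesterase gene CES1, from 20.7 ± 0.648 to 0.503 ± 0.345, and the neuronal microtubule gene MAP2, from 41.6 ± 1.14 to 2.72 ± 0.285 (-3.92 ± 0.11). GAS2, from 9.02 ± 0.786 to 0.717 ± 0.161 CPM (-3.63 ± 0.23), was lower likewise. TNFSF15, a TNF family ligand, rose from 3.03 ± 0.718 to 27.4 ± 1.43 CPM (3.17 ± 0.16), SUSD2 from 8.96 ± 0.492 to 42.4 ± 3.98 (2.24 ± 0.098) and the tenascin gene TNC from 0.634 ± 0.594 to 6.43 ± 0.697. ITGA11 (2.45 ± 0.17) was also higher.

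In the list of ER chaperones and unfolded protein response genes, 18 of 20 were higher in shNRF2 and 1 lower (median 0.44, camera adjusted p = 6.4e-13), with HERPUD1 at 1.31 ± 0.070, SYVN1 at 1.05 ± 0.13 and HYOU1 at 0.71 ± 0.068. 17 of 24 stress response genes were higher and 1 lower (camera adjusted p = 2.2e-09), NUPR1 by 1.07 ± 0.075 and DDIT3 by 0.72 ± 0.093. 19 of 27 heat shock genes were lower (21 adjusted over the list alone) and 2 higher (median -0.36, camera adjusted p = 1.2e-10), HSPA1A at -0.95 ± 0.067. HSF1 was at -0.23 ± 0.11 (edgeR adjusted p = 0.099) and passed only without shNRF2 DMSO replicate 1 (adjusted p = 0.0097). In the autophagy list 13 of 24 were lower and 2 higher (3 adjusted over the list alone; camera adjusted p = 5.8e-06), with SQSTM1 at -1.27 ± 0.047, GLA at -0.98 ± 0.065 and CTSL at -0.82 ± 0.050. 10 of 20 iron genes were lower and 3 higher (camera adjusted p = 0.0027), with the iron exporter gene SLC40A1 at -1.40 ± 0.12 and FTL at -0.99 ± 0.058. 13 of 20 hypoxia and glycolysis genes were lower and 2 higher (camera adjusted p = 6.1e-04), with EGLN3 at -2.34 ± 0.14. COL5A1 (1.53 ± 0.073), FN1 (1.03 ± 0.074) and EGR1 (1.18 ± 0.072) were higher, and the efflux pump gene ABCG2 (-1.83 ± 0.14) and GSTP1 (-0.74 ± 0.057) lower. Metallothionein MT2A was higher (0.92 ± 0.052).

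28 of 30 ribosomal protein genes (median -0.42) and 25 of 31 proteasome genes (26 adjusted over the list alone; median -0.28) were lower in shNRF2 in DMSO. Both calls (camera adjusted p = 6.4e-13 and 1.5e-07) were lost with an estimated correlation (adjusted p = 0.22 for each). RPS24 was at -0.61 ± 0.063 and PSMA4 at -0.48 ± 0.056, and ribosomal protein genes share reads with many processed copies. The 30 ribosomal protein genes took 2.08 ± 0.140% of counts in shNC DMSO and 1.71 ± 0.0856% in shNRF2 DMSO. Calls for higher S phase, mitosis, immediate early, mesenchymal and mitochondrial genes were also lost with an estimated correlation (adjusted p = 0.061, 0.069, 0.30, 0.21 and 0.48). Alveolar type 2 genes had a median of 0.11 and a test pointing down, without a camera call. The mitochondrial list was also lost without shNC DMSO replicate 2 (adjusted p = 0.086) or 3 (0.051) or shNRF2 DMSO replicate 2 (0.052). Over all genes 2636 were higher and 2872 lower, 395 and 377 of them at least 2-fold, and library totals gave 3226 and 2266.

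**Figure D3:**
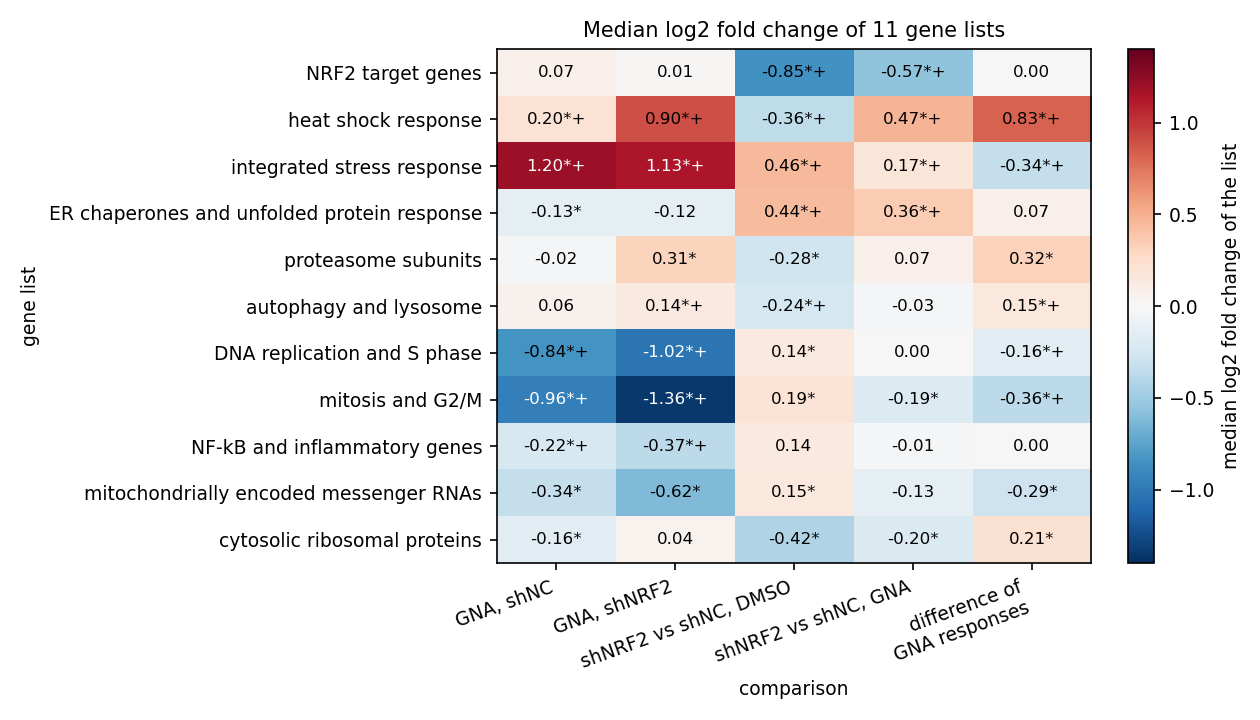
Median log2 fold change of 11 gene lists (rows) in the 5 comparisons (columns), on a colour scale from -1.4 to 1.4; * marks a camera adjusted p under 0.05 and + a list that also passed with an estimated correlation. Heat shock genes have medians of 0.20 and 0.90 with GNA in shNC and shNRF2, and NRF2 target genes of -0.85 and -0.57 between the lines in DMSO and GNA.

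Under GNA, the shNRF2 line still had lower NRF2 targets, while its heat shock genes were higher than in the control line. 30 of 34 NRF2 targets were lower (31 adjusted over the list alone) and 1 higher (median -0.57, camera adjusted p = 3.0e-60). AKR1B10 was at -1.95 ± 0.045, AKR1C1 at -1.65 ± 0.051, GCLM at -1.01 ± 0.068, NQO1 at -0.83 ± 0.048 and TXNRD1 at -0.83 ± 0.043. HMOX1 was closer to the control line, at -0.23 ± 0.068 (95% interval -0.39 to -0.075, edgeR adjusted p = 0.012). That call was lost without shNC GNA replicate 3 (adjusted p = 0.082) or shNRF2 GNA replicate 1 (adjusted p = 0.074) and with limma on FPKM. 22 of 27 heat shock genes were higher (24 adjusted over the list alone) and 0 lower (median 0.47, camera adjusted p = 7.6e-54), with HSPA1A at 2.16 ± 0.060, HSPA6 at 1.81 ± 0.063 and DNAJB1 at 1.48 ± 0.054. HSF1 was at -0.28 ± 0.10 (edgeR adjusted p = 0.042), a call lost with DESeq2 (adjusted p = 0.068) and under 4 other settings. It was also lost without shNC GNA replicate 2 (adjusted p = 0.089) or 3 (0.17) and without shNRF2 GNA replicate 2 (0.23) or 3 (0.056). 16 of 20 ER chaperone and unfolded protein response genes were higher and 1 lower (camera adjusted p = 2.8e-17). Among the higher was HSPA5, which encodes BiP, from 1431 ± 60.2 to 2967 ± 75.5 CPM (1.05 ± 0.051). MAP2 (-4.07 ± 0.095), HPD (-3.37 ± 0.10) and KRT6A (-3.44 ± 0.19) were among the steepest falls. TNC rose from 0.372 ± 0.337 to 6.46 ± 0.700 CPM, and TNFSF15 (2.37 ± 0.19) and SUSD2 (1.90 ± 0.11) were higher again.

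Stress response genes were higher in 10 (12 adjusted over the list alone) and lower in 3 of 24 cases (4 alone; camera adjusted p = 0.0057), DDIT3 by 0.85 ± 0.071 and NUPR1 by 0.66 ± 0.060. In the metallothionein list, whose measured members include MTF1 and SLC30A1, 2 of 4 genes were higher (camera adjusted p = 9.6e-04), MT2A by 1.13 ± 0.052. ABCB1 was higher (0.80 ± 0.091) and ABCG2 lower (-1.50 ± 0.13), GDF15 higher (0.76 ± 0.077) and the NF-kB inhibitor gene NFKBIA lower (-0.84 ± 0.068). PLK2 (-0.93 ± 0.048), SLC40A1 (-1.69 ± 0.11) and CTSB (-0.67 ± 0.046) were lower too. Calls for lower iron, p53 target, mitotic, interferon-stimulated, hypoxia and ribosomal protein genes were lost with an estimated correlation (adjusted p = 0.099, 0.089, 0.28, 0.28, 0.071 and 0.63). The p53 target call was also lost without shNC GNA replicate 3 (adjusted p = 0.052). Signs of median, mean and test differed without a camera call for mesenchymal (-0.30, -0.20, up), NF-kB (-0.013, 0.023, up), S phase (-0.0017, 0.0042, down) and cisplatin genes (0.025, -0.033, down). In all 2010 genes were higher and 2080 lower, 212 and 362 of them at least 2-fold.

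Across genes, the response to GNA in shNC and in shNRF2 correlated with a Pearson r of 0.59 and a Spearman rho of 0.58. The slope was 0.68 of shNRF2 on shNC and 0.52 of shNC on shNRF2. Changes had an SD of 0.48 in shNC and 0.54 in shNRF2, so a slope under 1 does not show a smaller response in shNRF2. These comparisons share no library, and genes are not independent replicates, so no p-value is attached. Of the genes called in both lines, 1318 rose in both, where independent lists would share 382, and 1651 fell in both, against 429. NIBAN1, BEX2 and DDIT3 were among the shared rises and KIF20A and CCL2 among the shared falls. There were 77 genes called in opposite directions. The difference between the lines correlated across genes between DMSO and GNA with an r of 0.63 and a rho of 0.56. The slope was 0.55 of GNA on DMSO and 0.71 of DMSO on GNA. Here 1199 genes were higher in both, against 338 for independent lists, and 1440 lower in both, against 382, with 105 in opposite directions. AKR1B10, MAP2 and GCLM were lower in both treatments, and SUSD2 and TNFSF15 higher in both. The correlations depend on low-count genes: without the filter, over 38014 genes, they were 0.076 and 0.091.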

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

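The tests of scaling, of near-identical copies, of the starting level and of a shared recovery of NRF2 targets were chosen only after the result was seen, as was the condition that a value pass its bound by more than its spread.

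The response to GNA differed between the lines by a test of the difference itself for 10 gene lists and 49 of the genes named in the report. The median difference, shNRF2 minus shNC on the log2 scale, was 0.83 for heat shock genes, 0.32 for proteasome subunits, 0.21 for ribosomal protein genes and 0.15 for autophagy and lysosome genes. It was -0.36 for mitosis, -0.34 for the integrated stress response, -0.29 for mitochondrially encoded messenger RNAs, -0.27 for immediate early genes, -0.20 for mesenchymal and matrix genes and -0.16 for S phase. The differences for proteasome, ribosomal protein, mitochondrial, immediate early and mesenchymal genes were not called with an estimated correlation. In DMSO each of these 10 lists differed between the lines in the opposite direction, for example proteasome (median -0.28), ribosomal protein (-0.42) and mitotic genes (0.19). The difference of responses is the difference between the lines under GNA minus that in DMSO, so opposite signs arise in part by construction. For lists other than heat shock, whether the starting level accounts for the difference of responses was not tested.

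Genes with a higher response in shNRF2 were HSPA1A (3.11), HSPA1B (2.94), MYH14 (2.25), DNAJB1 (1.66), HMOX1 (1.19), ABCB1 (1.09), SQSTM1 (0.94), NIBAN1 (0.92), GABARAPL1 (0.81), BEX2 (0.80), MAP1LC3B (0.76) and CACYBP (0.73). HSPA6 had a fitted difference of 2.99, which depends on the prior count because its DMSO counts were few. That call was lost without shNC DMSO replicate 1 (adjusted p = 0.13) or 2 (0.068) or shNRF2 DMSO replicate 2 (0.083). Smaller ones were NDRG1 (0.70), PSMD11 (0.59), AHSA1 (0.55), PSMC4 (0.53), FTL (0.50), HSPA4 (0.45), GDF15 (0.44), HSPA5 (0.42), PPP1R15A (0.42), PSMD13 (0.42), GLA (0.35), GADD45A (0.32), PSMA4 (0.32) and CTSL (0.27). Genes with a lower response in shNRF2 were CHAC1 (-1.72), CCN2 (-1.49), THBS1 (-1.17), EGR1 (-1.001), FOSB (-0.98), SLC7A5 (-0.95), CCN1 (-0.78), PCK2 (-0.74), NFKBIA (-0.68), CENPF (-0.64), NCAPG (-0.64) and TOP2A (-0.57). Smaller ones were HERPUD1 (-0.54), FANCD2 (-0.53), PLK2 (-0.52), NUPR1 (-0.41), CDH1 (-0.39), PLK1 (-0.36), ABCC3 (-0.36), SLC7A11 (-0.35), MT-ND3 (-0.32) and NFE2L2 (-0.30). The CHAC1 value, too, rests on few DMSO counts. The calls of CHAC1, FANCD2, CDH1, GADD45A, GDF15, SLC7A5 and NFE2L2 were each lost under at least 1 alternative or without 1 library. That of CHAC1, for example, was lost without shNC DMSO replicate 3 (edgeR adjusted p = 0.067). Alternatives were not run on the difference of responses for every gene listed here, so a gene not named as lost need not be stable.

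Heat shock genes rose more with GNA in shNRF2 than in shNC. The list median was lowest of 4 scalings with library totals, at 0.79, where the median of all genes moved by -0.039, so the choice among these scalings does not account for it. After removal of a length and GC trend it was 0.81, against such a trend as the whole cause. The 16 members without near-identical copies had a median difference of 0.78, against reads exchanged between copies as the whole cause. A lower starting level in shNRF2 would leave both lines at one level under GNA, but the list was 0.47 higher in shNRF2 there. This argues against a lower start as the whole cause. The list did start lower in shNRF2 in DMSO, so a lower start may still be part of the difference. A stronger heat shock response where NRF2 is low may be biological, as a hypothesis: with 1 hairpin line, the effects of NRF2, of the hairpin and of the line stay open and untested.

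HMOX1 also rose more in shNRF2, by 1.15 in the lowest of the 4 scalings (library totals), against the choice among them as the whole cause. The other 27 NRF2 targets lower in shNRF2 in DMSO had a median difference of responses of 0.0074 with an SD of 0.46 between genes, and 4 were called higher and 2 lower. The lowest, SRXN1 at -1.81, named after its values were seen, varied between libraries (14.5 ± 8.09 CPM in shNC GNA), and without it the median was 0.013 and the SD 0.29. Their median difference between the lines was -0.94 in DMSO and -0.64 under GNA. The median lies more than 2 SDs below the 1.19 of HMOX1, which argues against a recovery of these targets as large as that of HMOX1, while a smaller recovery of part of them stays open. HMOX1 began lower in shNRF2 and under GNA stood at -0.23 against shNC on the log2 scale, so a lower start with a nearly shared end level remains a candidate explanation. Whether regulators of HMOX1 other than NRF2 account for its larger rise in shNRF2 was not tested.

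Ribosomal protein and proteasome genes were lower in shNRF2 in DMSO, though both list calls were lost with an estimated correlation. The joint median of these genes was nearest 0 with library totals, at -0.29, where the median of all genes moved by 0.054, and it was -0.31 after removal of a length and GC trend. These values argue against the choice among the 4 scalings and against such a trend as the whole cause. The DMSO group means lay 4.46 pooled SDs apart (spread 1.11, bound 4), so the bound set for drift between libraries within a group did not decide, because the spread reaches it. The mean log2 CPM of these genes did not overlap between the groups. It was 7.64 to 7.82 in the shNC DMSO libraries and 7.36 to 7.48 in the shNRF2 DMSO libraries, a difference of means of -0.32 with a pooled SD of 0.072. A difference between the lines may be the source, and it stays untested as such.

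Among the 10 splits of 6 libraries in each comparison of 2 groups, 1 split, the real one, gave as many called genes: 4810 for GNA in shNC (highest other 0), 5274 for GNA in shNRF2 (highest other 1), 5508 for the lines in DMSO (highest other 1) and 4090 for the lines in GNA (highest other 0). Those splits are too few for a share under 0.05. For the difference of responses, 5 of 100 splits drawn from 200 gave as many genes as the real 1068, the real one included, with 2150 as the highest other. By this count chance is not excluded for the number of genes called. The 4 other splits at or above the real one all kept the lines apart in 1 treatment and mixed them in the other, so they contain the line difference, a structure of the samples. Of other kinds of split the highest gave 1. Splits that mix the groups move the difference between them into the spread within groups, which lowers the number of calls. The low counts of such splits, here and in the comparisons of 2 groups, are therefore not a chance level.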

How the results depend on the processing

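Library totals were the alternative chosen only after the data were seen. Over all alternatives 0 results on genes, lists or correlations reversed, while counts of genes could not be labelled as reversed. The balance of such counts did shift. GNA in shNC had 2284 genes higher and 2526 lower in the main fit, and 2635 and 2184 with upper-quartile factors. Of 276 results on named genes 22 changed side of the threshold under at least 1 alternative. Of 120 list results 49 did so with camera and 61 with fry included, which tests against no change. Of the 25 main counts and values 2, both on NFE2L2, changed side of the threshold, and 12 others, which have no threshold, moved. An estimated correlation ended 30 list calls. The cause was not tested unless given. GNA in shNC had 3543 genes higher and 1542 lower with library totals, and 1430 and 1417 lower with limma on log2(FPKM + 1) and log2(FPKM + 0.1), units scaled by the same totals. Without 1 library it had 1770 to 2227 higher and 2048 to 2574 lower. For the difference of responses limma gave 301 and 274 genes higher and, with 0.1, 329 lower; leaving out 1 library gave 381 to 764 higher and 315 to 673 lower. The NFE2L2 call in shNC was lost with no filter (0.18, adjusted p = 0.073), DESeq2 (0.16, adjusted p = 0.065) and the replicate block (0.17, adjusted p = 0.057), with a leave-one-out range of 0.13 to 0.20. For the difference it was lost with no filter (-0.31), limma (-0.28 and -0.33) and the block (-0.30), with a range of -0.33 to -0.25. Across genes, the GNA responses of the lines correlated with r and rho of 0.076 and 0.17 with no filter (slope 0.079), 0.12 and 0.18 with DESeq2 (slope 0.12), 0.65 and 0.62 with 1 CPM in 3 libraries, 0.71 and 0.64 with limma on log2(FPKM + 1) (slope 0.84), 0.63 (r) with 0.1 and 0.72 and 0.76 over genes past the threshold in either comparison (slope 0.85). Without 1 library r was 0.519 to 0.551, rho 0.538 to 0.566 and the slope 0.535 to 0.663. With no filter and in DESeq2 more low-count genes enter by construction. Leaving out 1 library also brought more genes past the filter, 16027 to 16138 against 15653, so those fits differ from the main one in their genes as well. Shared rises were 2045 and shared falls 1081 with library totals, and shared falls 1006 and 1010 with limma. The differences between the lines correlated with 0.091 and 0.17 (slope 0.088) with no filter, 0.14 and 0.19 (slope 0.14) with DESeq2, 0.68 and 0.59 with 1 CPM in 3 libraries, 0.69 and 0.60 with limma on log2(FPKM + 1) and 0.74 and 0.74 over genes past the threshold. Without 1 library r was 0.567 to 0.586 and rho 0.523 to 0.548. Depth limits genes with few counts, such as HSPA6 in DMSO. In the simulation, which changed far fewer genes than were called in the data, 37.2% of 1.5-fold differences of responses were recovered.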

Other observations

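The lists of YAP targets, cytosolic aminoacyl-tRNA synthetases and nuclear respiratory chain subunits, and their tests, were chosen only after the data were seen. CCN2 and THBS1 had lower responses to GNA in shNRF2, and both are YAP targets. CCN1 (-0.78) and TGFB2 (-0.38, edgeR adjusted p = 0.23), YAP targets too, were left out of the list along with these 2. Of the 20 YAP targets tested, 4 had a higher and 5 a lower response, with a median difference of -0.17. Camera gave an adjusted p = 0.018 with the preset correlation, and p = 0.25 (adjusted p = 0.47 over 15 tests) with an estimated one, so whether there is a group response stays open.

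Cytosolic aminoacyl-tRNA synthetase genes may rise with the integrated stress response: the lower of their medians in the 2 lines was 0.20, in shNRF2. Camera with the preset correlation called the list in shNC (adjusted p = 1.5e-08) and shNRF2 (adjusted p = 1.7e-04). With an estimated correlation p = 0.010 in shNC and 0.055 in shNRF2, and over 15 tests the adjusted p = 0.15 and 0.33, so the adjusted values did not pass. Of 20 genes, 11 rose in each line, 5 fell in shNC and 2 fell in shNRF2. Nuclear genes of the respiratory chain may fall together with mitochondrially encoded messenger RNAs under GNA. Their median in shNRF2 was -0.30, past the bound set for it, with 27 of 35 lower and 0 higher, although with an estimated correlation p = 0.10 (adjusted p = 0.39 over 15 tests). In shNC 23 of the 35 were lower and 0 higher (median -0.33), and camera with the preset correlation called the list in both lines (adjusted p = 1.5e-08 in shNC and 7.3e-07 in shNRF2), while with an estimated correlation it passed in neither. The larger fall of mitochondrially encoded messenger RNAs in shNRF2 (median difference -0.29) was not seen in the nuclear genes. Their median difference was -0.021, with 0 higher and 0 lower (camera adjusted p = 0.74).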
